A study of Mus musculus with 39 samples.

How the data were processed

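Lungs of 39 female mice of the outbred strain Crlj:CD1(ICR) were measured, each on its own array. P-values of single genes and of quantities measured per animal thus measure the spread between animals. Per the labels' protocols, the animals ate powdered diet with permethrin (5000 or 10000 ppm), isoniazid (2500 ppm) or neither for 7 or 14 days, lungs were kept in an RNA stabilization solution, and biotin-labelled cRNA made from total RNA with a kit that primes at the 3' end was hybridized to Affymetrix arrays. The groups and replicate numbers follow the sample titles. Each group holds 5 animals, except permethrin 10000 ppm at 14 days with 4. Ages were 11 weeks in the 7-day groups and 12 weeks in the 14-day groups, so age and duration rise together.

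The deposited values are signal intensity in linear units, 1 value per probe set and array, which the authors computed with MAS5 per the submitters' processing notes. The version is not given in the sources used here. After the authors' scaling, the trimmed mean of each array is 100.0. The 45101 probe sets of the arrays were present, of which 64 are controls, 34945 carry 1 gene symbol, 932 several and 9160 none. The named probe sets stand for 18193 genes. Image processing, background subtraction and probe summary were done by the authors and could not be varied here.

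Array medians ran from 17.4 to 26.2, a ratio of 1.51, which is above the limit set before the data were examined for using the deposited scaling as it is. By that rule the log2 values were quantile normalized, with no pseudocount. Each gene is represented by its probe set of highest mean signal, and genes were tested where that mean lay in the upper 60% of all probe sets other than controls (mean log2 signal of at least 3.43, a signal of 10.8), which left 13020 genes. Quantile normalization removes any change shared by most genes, and ties the brightest probe sets to the top of the scale. For arrays, their number per group limits the precision.

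A linear model with 8 group means was fitted to all 39 arrays in R 4.3.3 with limma 3.58.1 (empirical Bayes with a mean-variance trend), and data handling used the data.table package, version 1.17.8. There were 14 comparisons: each treatment against the control of its own time, the mean of both times for each treatment, the higher against the lower permethrin dose, the higher dose against isoniazid, and the change of each treatment effect from 7 to 14 days. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 13020 genes of each comparison, with an adjusted p of 0.05 as threshold. Errors of fold changes are standard errors (SE) of this model. The step from values to calls was tested on simulated data in which 200 of 13020 genes were changed.

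Before the data were examined, 46 gene lists were written that cover foreign-compound metabolism, stress and hormone responses, growth, the cell types of lung, and other tissues that can be taken with it. They were tested with camera of limma at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, which tests whether a list's genes move one way on balance. Camera compares a list's genes with all other genes, so its p-values also rest on the spread over genes, not on the animals alone. List p-values were adjusted over the 46 lists. For each list, members past the threshold are counted in both ways: adjusted over all genes tested, and adjusted over the list alone.

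The rule for named genes was also fixed before the data were examined. Against the control of the same time it takes, among genes past the threshold whose treated animals all lie on one side of the control mean, the 10 largest rises and the 10 largest falls. For the other comparisons it takes 5 of each, and where no gene passed, the 5 smallest p-values, given as not past the threshold. It adds up to 4 members of each fixed list, those with the smallest p among members past the threshold. Always given against the control of the same time are Cyp2b10, Cyp2f2, Scgb1a1, Cyp1a1, Mki67, Top2a and Sftpc. Genes named outside the rule are marked as chosen after their values were seen.

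Means of single quantities (the liver and cardiac scores, the 3' to 5' ratio of the Actb and Gapdh control probe sets, and a clock score) were compared by exact two-sided permutation tests. The liver and cardiac scores are mean log2 signals of genes abundant in those tissues. Alternatives planned before the data were examined were quantile normalization (used throughout by the rule above), centring each array on its median, a pseudocount of 3.98, no filter, a filter keeping the upper 40%, every probe set tested, only the compared groups in the model, replicate number as a block, array weights, an estimated correlation, controls split between treatments, and leaving out each animal. Alternatives chosen after seeing the data were the deposited scaling without quantile normalization, leaving out 7 arrays with a Gapdh 3' to 5' log2 ratio above 0.7, and using as covariates the 3' to 5' ratio, the cardiac and liver scores, or the clock score. Probe sets with several symbols or none were left out of the comparisons, since no single gene can be given for them.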

Results

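Gene expression was measured in the lungs of female Crlj:CD1(ICR) mice fed permethrin or isoniazid for 7 or 14 days. Permethrin is a pyrethroid insecticide that acts on voltage-gated sodium channels. Isoniazid is an antituberculosis drug that the labels name as a positive control for tumours. The comparisons ask which genes change with each compound, whether the changes depend on permethrin dose and on duration, and whether both compounds change the same genes. The 39 arrays fall into 8 groups: control, permethrin 5000 ppm, permethrin 10000 ppm and isoniazid 2500 ppm, each at 7 and at 14 days. Each group holds 5 animals, except permethrin 10000 ppm for 14 days with 4, and this number limits the precision. No arrays were identical, and correlations between arrays ran from 0.917 to 0.983.

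RNA integrity and the share of other tissues varied between animals. The Gapdh 3' to 5' log2 ratio, which rises as RNA degrades, was above 0.7 in 7 arrays, all at 14 days. They were control replicates 4 and 5, permethrin 5000 ppm replicates 4 and 5, permethrin 10000 ppm replicate 3, and isoniazid replicates 3 and 5. Mean log2 signal of abundant liver genes was 3.87 (SD 0.49, n = 5) with isoniazid at 14 days and 5.73 (SD 0.55, n = 5) in the controls, with a two-sided exact permutation p of 0.00794 (0.238 after adjustment over 30 such tests). Mean log2 signal of cardiac muscle genes was 6.45 (SD 0.63, n = 5) in the 14-day controls. It was 7.32, 7.37 and 7.36 with permethrin 5000 ppm, permethrin 10000 ppm and isoniazid. The exact permutation p-values were 0.0317, 0.151 and 0.0476, which became 0.317, 0.595 and 0.357 after adjustment.

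**Figure D1:**
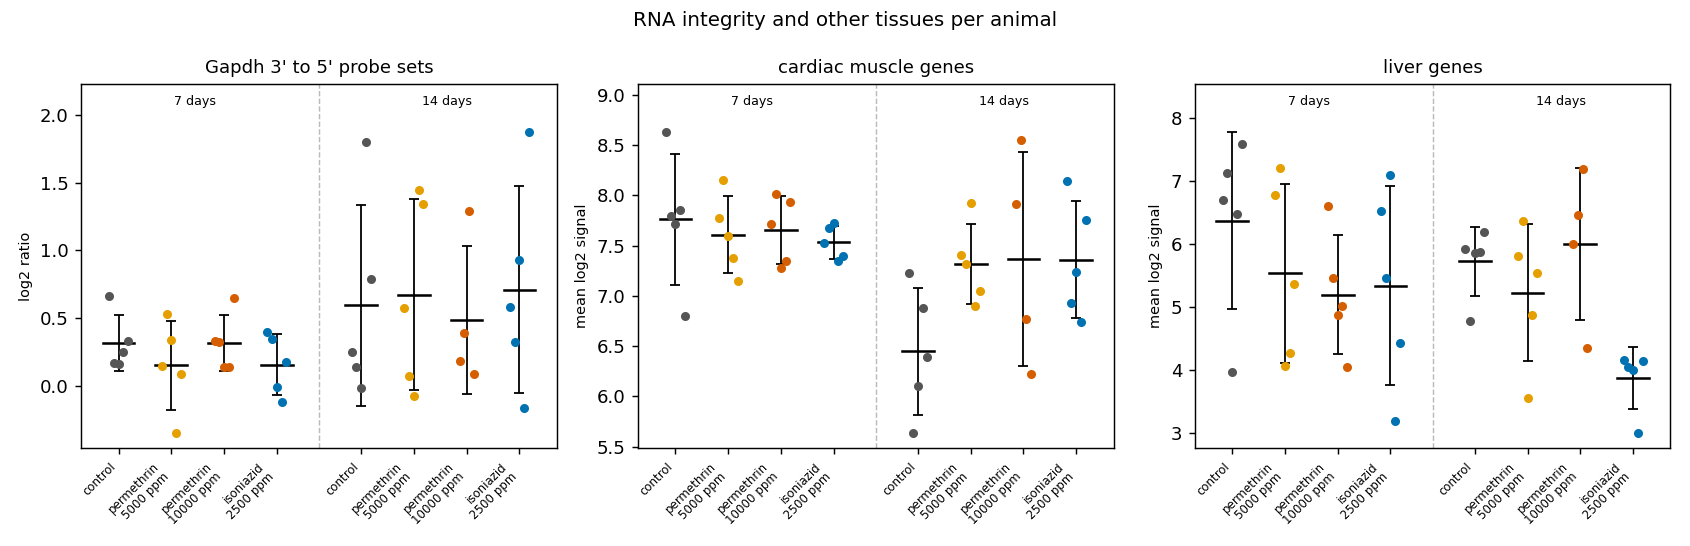
Gapdh 3' to 5' log2 ratio, mean log2 signal of cardiac muscle genes and mean log2 signal of liver genes in each of 39 animals, with points for animals, lines for group means and bars for SD. The ratio exceeds 0.7 in 7 animals at 14 days, the cardiac signal averages 6.45 in 14-day and 7.76 in 7-day controls, and the liver signal averages 3.87 with isoniazid at 14 days.

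After 7 days, permethrin raised genes that detoxify electrophiles and keep thiols reduced. At 10000 ppm the glutathione S-transferase Gsta2 rose 5.79-fold (log2 fold change 2.53, SE 0.21, adjusted p = 5.53e-10, n = 5 and 5). The aldehyde dehydrogenase Aldh3a1 rose 5.45-fold (log2 2.45, SE 0.29), the carboxylesterase Ces1g 4.70-fold (log2 2.23, SE 0.28) and the quinone reductase Nqo1 3.86-fold (log2 1.95, SE 0.23). All 5 treated animals lay above the control mean for these 4 genes at both doses. At 5000 ppm Gsta2 rose 3.46-fold (log2 1.79, SE 0.21, adjusted p = 6.25e-06), Ces1g 3.69-fold, Nqo1 3.12-fold and Aldh3a1 2.84-fold. Sulfiredoxin Srxn1 rose 3.03-fold at 10000 ppm and 1.81-fold at 5000 ppm, and thioredoxin reductase Txnrd1 rose 2.68-fold and 2.05-fold. The glutathione peroxidase Gpx2, the biliverdin reductase Blvrb, the carbonyl reductase Cbr3 and the epoxide hydrolase Ephx1 also rose at both doses, by 3.15-fold, 3.32-fold, 2.60-fold and 1.91-fold at 10000 ppm. At 10000 ppm the glutamate-cysteine ligase subunit Gclc rose 2.79-fold and the efflux transporter Abcc3 rose 1.64-fold. Id4, an inhibitor of helix-loop-helix factors, fell by 0.57 on the log2 scale (SE 0.12, adjusted p = 0.0205).

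In all, 31 genes passed the threshold at 10000 ppm for 7 days (30 higher, 1 lower) and 12 at 5000 ppm (all 12 higher). All 12 were among the 30, and the doses share their controls. Simulated data without effects gave 0 shared genes. The doses shared controls there too, but noise was drawn independently for each gene. Those data thus cannot show what noise common to many genes adds. The NRF2 and glutathione list holds targets of the transcription factor that answers oxidative and electrophilic stress. Of its 31 members, 17 rose at 10000 ppm (22 adjusted over the list alone) and 8 at 5000 ppm (21 adjusted over the list alone). Its median log2 fold changes were 0.71 and 0.46 (camera adjusted p = 8.68e-08 and 2.93e-06 with an estimated correlation). CAR and PXR are nuclear receptors for foreign compounds, and 5 of 19 of their targets rose at 10000 ppm (median 0.24, adjusted p = 4.99e-05 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. At 5000 ppm 3 rose, 4 adjusted over the list alone (median 0.12, adjusted p = 0.00182 with an estimated correlation). With no filter on dim probe sets the median of CAR and PXR target genes, permethrin 5000 ppm against control, 7 days, was -0.04. Drug-metabolizing enzymes of lung had 8 and 5 of 44 members higher (adjusted p = 1.35e-05 and 0.000131 with an estimated correlation). Adjusted over the list alone, 15 and 9 were higher and 1 lower at each dose.

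Aryl hydrocarbon receptor targets were called higher as a list at 10000 and 5000 ppm (adjusted p = 0.0104 and 0.0162 with an estimated correlation), with medians of only 0.14 and 0.08. With no filter on dim probe sets the median of aryl hydrocarbon receptor target genes, permethrin 10000 ppm against control, 7 days, was -0.09. The 2 of 9 past the threshold were Nqo1 and Aldh3a1, and adjusted over the list alone 3 and 2 were higher and 1 lower. Cyp1a1, a P450 of this list, had log2 fold changes of -1.37 (SE 0.37, adjusted p = 0.231) and -1.23 (SE 0.37, adjusted p = 0.822), with 0 of 5 treated animals above the control mean. Cholesterol synthesis genes were lower as a list at 5000 ppm (median -0.19, adjusted p = 0.0499 with an estimated correlation), with 0 of 20 past the threshold, also adjusted over the list alone. At 10000 ppm p53 targets were higher as a list (median 0.14, adjusted p = 0.0377 with an estimated correlation), with 0 of 24 past the threshold, also adjusted over the list alone. Club cells of the airway carry many detoxifying enzymes, and 2 of 40 club cell markers rose at 10000 ppm (2 adjusted over the list alone). They were the retinaldehyde dehydrogenase Aldh1a1 (log2 0.28, SE 0.05) and the microsomal glutathione transferase Mgst1 (log2 0.23, SE 0.05). Cyp2b10, a CAR target of liver, had log2 fold changes of 0.06 and 0.07 (SE 0.09), and those of Cyp2f2, Sftpc, Mki67 and Top2a lay between -0.11 and 0.11. In limma 0 of 43 cell cycle genes passed at either dose, also adjusted over the list alone, where 410 and 259 of all genes had an unadjusted p under 0.05. Scgb1a1, the main secretory protein of club cells, sat at the ceiling of the normalized scale, where a change could not be read. The calls of Ces1f at 5000 ppm (log2 1.12) and of Mgst1 at 10000 ppm were each lost under 14 of 22 alternatives, and that of Id4, whose 2 other probe sets both had -0.22, under 8 of 22.

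**Figure D2:**
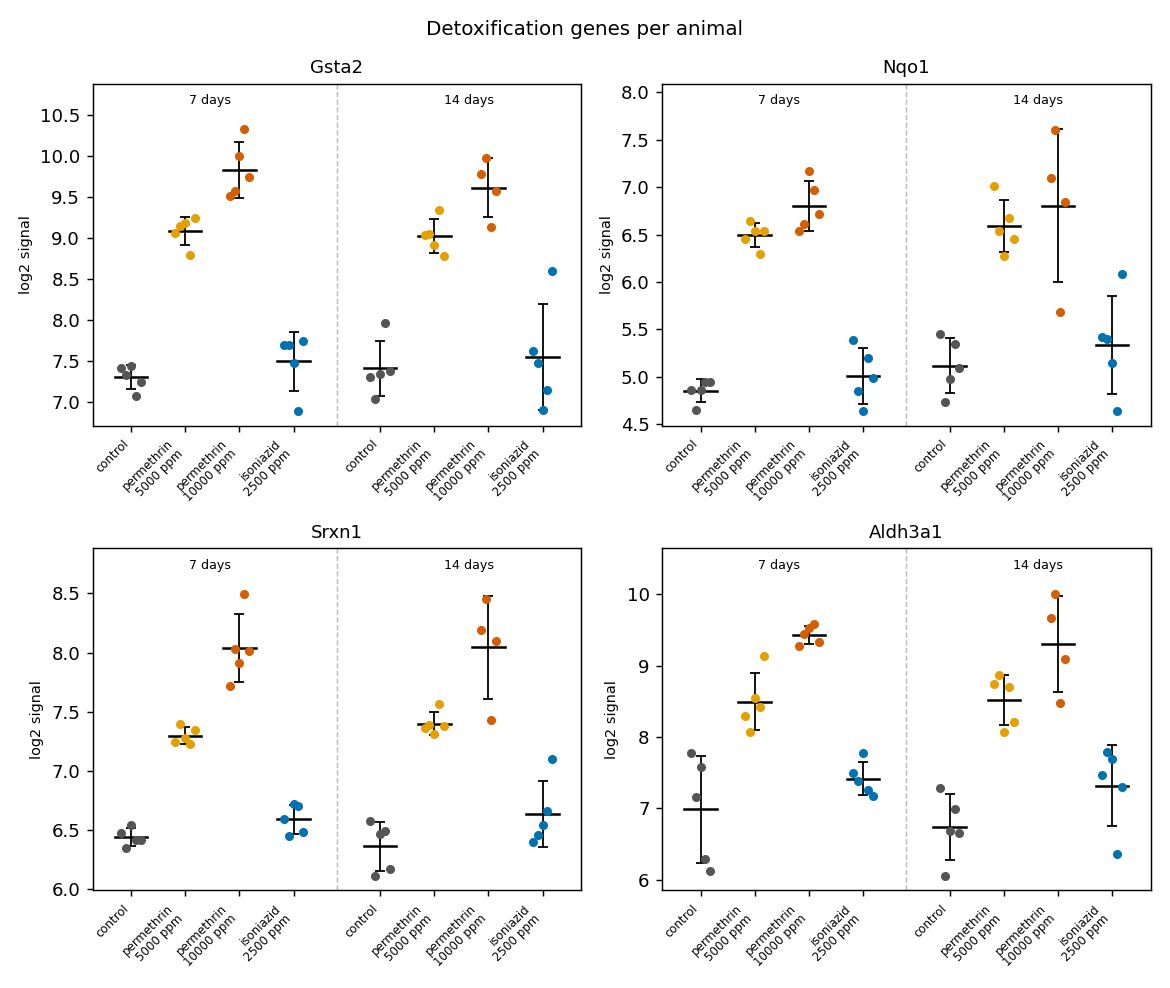
Log2 signal of Gsta2, Nqo1, Srxn1 and Aldh3a1 in each animal of the 8 groups, with points for animals, lines for means and bars for SD. At 7 days Gsta2 averages 7.30 in controls, 9.09 at 5000 ppm and 9.84 at 10000 ppm of permethrin.

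After 14 days of permethrin the largest rises again included detoxifying enzymes. At 10000 ppm (n = 4, against 5 controls) Aldh3a1 rose 5.97-fold (log2 2.58, SE 0.30, adjusted p = 1.24e-06), Ces1g 4.68-fold, Gsta2 4.63-fold (log2 2.21, SE 0.23, adjusted p = 6.44e-08) and Nqo1 3.22-fold. Srxn1 rose 3.21-fold (log2 1.68, SE 0.15, adjusted p = 2.63e-09), and all 4 treated animals lay above the control mean for these genes. At 5000 ppm (n = 5 and 5) Ces1g rose 4.25-fold (log2 2.09, SE 0.28, adjusted p = 3.3e-05), Aldh3a1 3.44-fold, Gsta2 3.07-fold, Nqo1 2.77-fold and Srxn1 2.06-fold. Txnrd1, Gpx2, the glutathione transferase Gstm1, Ephx1, Aldh1a1 and the peroxisomal oxidase Acox2 rose at both doses. At the higher dose they rose 2.61-fold, 2.82-fold, 1.72-fold, 1.55-fold, 1.24-fold and 2.61-fold. Blvrb, Cbr3, Abcc3 and Mgst1 rose at 10000 ppm, by 2.85-fold, 2.26-fold, 1.58-fold and 1.20-fold. Orm1, an acute-phase plasma protein abundant in liver, rose 5.55-fold at 10000 ppm (log2 2.47, SE 0.48, adjusted p = 0.00489). The liver signal of that group was 6.01, against 5.73 in controls (exact permutation p = 0.667, n = 4 and 5). Cyp1a1 fell by 2.06 on the log2 scale at 10000 ppm (SE 0.39, adjusted p = 0.00477), to a treated mean of 3.19, which is dimmer than the filter's mean signal of 3.43. At 5000 ppm it had a log2 fold change of -0.57 (SE 0.37, adjusted p = 0.977).

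At 14 days 28 genes passed at 10000 ppm (27 higher, 1 lower) and 17 at 5000 ppm (16 higher, 1 lower). The gene lower at 5000 ppm was the predicted gene Gm19990 (log2 -1.12, SE 0.24). Of the genes called higher, 15 were shared between the doses, which share their controls. The simulated data, with noise drawn gene by gene as at 7 days, again gave 0 shared genes and decide nothing here. In the NRF2 and glutathione list 13 of 31 members rose at 10000 ppm (26 adjusted over the list alone) and 10 at 5000 ppm (18 adjusted over the list alone). Its medians were 0.76 and 0.50 (adjusted p = 7.44e-06 and 0.000155 with an estimated correlation). CAR and PXR targets had 5 and 4 of 19 members higher (6 and 5 adjusted over the list alone, adjusted p = 0.0015 and 0.00721 with an estimated correlation). Drug-metabolizing enzymes had 8 and 6 of 44 higher (18 and 12 adjusted over the list alone, adjusted p = 0.000176 and 0.000262 with an estimated correlation), and 1 was lower at the higher dose. Aryl hydrocarbon receptor targets at 5000 ppm had a median of -0.01 beside a mean of 0.28 and an upward call (adjusted p = 0.00986 preset, adjusted p = 0.0759 with an estimated correlation). Club cell markers were higher as a list at 5000 ppm (median 0.21, 1 of 40 past the threshold, 2 adjusted over the list alone, adjusted p = 0.0206 with an estimated correlation), with 34 members positive. Ciliated cell markers there had 37 of 43 positive and 0 past the threshold, also adjusted over the list alone (median 0.23, preset adjusted p = 8.21e-06, adjusted p = 0.535 with an estimated correlation). Cyp2b10, Cyp2f2, Sftpc, Mki67 and Top2a did not pass at either dose (log2 fold changes from -0.10 to 0.41). In limma 0 of 43 cell cycle genes passed, also adjusted over the list alone, where 787 and 680 of all genes had an unadjusted p under 0.05.

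The 30 cardiac muscle genes had medians of 0.88 and 0.91 at 10000 and 5000 ppm for 14 days, with 0 past the threshold in limma. Adjusted over the list alone 0 and 12 passed, and the calls with the preset correlation were lost otherwise (adjusted p = 0.239 and 0.154 with an estimated correlation). Without the 7 arrays of high 3' to 5' ratio, which leaves fewer animals, 33 genes passed at 10000 ppm (23 shared with the 28) and 10 at 5000 ppm (9 shared with the 17). Cyp1a1, permethrin 10000 ppm against control, 14 days, then had a log2 fold change of -1.8 (adjusted p = 0.119, range over its alternatives 0.00176 to 0.177). With cardiac and liver signal as covariates 15 and 5 genes passed, all among those above, and both of these alternatives were chosen after seeing the data. At 5000 ppm Acox2 lost its call under 16 of 22 alternatives, Gm19990 and Aldh1a1 under 13, Ephx1 under 10, Fetub (fetuin-B, log2 0.91) under 10 of 21 and the neuropeptide gene Pth2 (log2 1.78) under 9 of 21, and at 10000 ppm Mgst1 under 11 of 21. The count at 5000 ppm was 8 without control replicate 2, permethrin replicate 1 or permethrin replicate 4, and 10 without control replicate 5. At 10000 ppm it was 17 without permethrin replicate 2 and 48 without permethrin replicate 4.

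Over the mean of both times, 65 genes passed at 10000 ppm (59 higher, 6 lower) and 29 at 5000 ppm (all 29 higher). Aldh3a1 rose 5.70-fold and 3.13-fold at the higher and lower dose, Gsta2 5.18-fold and 3.26-fold, Ces1g 4.69-fold and 3.96-fold, and Nqo1 3.53-fold and 2.94-fold. At 10000 ppm Srxn1 rose 3.12-fold, and at 5000 ppm Gpx2 rose 2.48-fold. At 10000 ppm Cyp1a1, dim at 14 days as given above, fell by 1.71 on the log2 scale (SE 0.27, adjusted p = 0.00011). The acyl-CoA oxidase-like gene Acoxl fell by 0.53 (SE 0.12, adjusted p = 0.0225), the AMP-activated kinase subunit Prkab2 by 0.45 (SE 0.10, but -0.08 and -0.22 in its 2 other probe sets), Kcnip4 by 1.01 (SE 0.25) and Gm19990 by 0.71 (SE 0.17). Of the NRF2 and glutathione list, 20 of 31 members rose at 10000 ppm (27 adjusted over the list alone) and 17 at 5000 ppm (22 adjusted over the list alone). Its medians were 0.69 and 0.50 (adjusted p = 5.21e-08 and 1.86e-07 with an estimated correlation). At 5000 ppm cholesterol synthesis genes were lower as a list (median -0.18, 0 of 20 past the threshold, 6 lower adjusted over the list alone, adjusted p = 0.0274 with an estimated correlation). The calls of Kcnip4, Gm19990 and Prkab2 were lost under 21 of 30, 17 of 31 and 13 of 31 alternatives. Without permethrin 10000 ppm 14 days replicate 2 the higher dose gave 41 genes.

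The doses differed in 1 gene past the threshold over the mean of both times. Srxn1 was 1.62-fold higher at 10000 than at 5000 ppm (log2 0.69, SE 0.10, adjusted p = 0.000851). As a whole, the NRF2 and glutathione list was higher at the higher dose (median difference 0.23, adjusted p = 0.0388 with an estimated correlation), with 1 of 31 members past the threshold and 7 adjusted over the list alone. CAR and PXR targets had a median difference of 0.13 and a call that was lost (adjusted p = 0.26 with an estimated correlation), with 0 of 19 past the threshold in limma and 3 adjusted over the list alone. With only the permethrin groups in the model, which leaves fewer animals to estimate the spread, 0 genes passed in limma. Srxn1, permethrin 10000 ppm against permethrin 5000 ppm, mean of both times, then had an adjusted p = 0.0551 (range over its alternatives 4.12e-06 to 0.0551). The count was 4 without the 7 arrays of high 3' to 5' ratio, 2 without permethrin 5000 ppm 14 days replicate 4 and 4 without permethrin 10000 ppm 14 days replicate 3, and 436 genes had an unadjusted p under 0.05.

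Between 7 and 14 days the permethrin effects did not differ past the threshold for any gene. In limma 0 genes passed at either dose, with 371 at an unadjusted p under 0.05 at 5000 ppm and 293 at 10000 ppm. At 5000 ppm the smallest p-values were those of Dubr (log2 change of the effect 1.88, SE 0.44), Maoa (-0.57, SE 0.15), Pdp2 (0.66, SE 0.17), Pth2 (1.94, SE 0.52) and Mctp1 (-1.67, SE 0.45). At 10000 ppm they were those of Capn12 (-2.21, SE 0.57), Adamts5 (0.64, SE 0.17), Id4 (0.65, SE 0.18), Ppp1r3c (0.77, SE 0.23) and Abcf2 (-0.72, SE 0.21). The median of the NRF2 and glutathione list changed by -0.01 and -0.06 (adjusted p = 0.989 and 0.867 with an estimated correlation). Of the genes called higher, 24 were shared between the times at 10000 ppm (30 and 27 called) and 9 at 5000 ppm (12 and 16 called), against 0.0622 and 0.0147 for independent calls. The tests on simulated data recovered 65.7% of genes whose effect changed by 1 on the log2 scale at 10000 ppm and 62.7% at 5000 ppm. These shares hold for 200 genes changed at once in independent noise, and fewer changed genes would be recovered less often. Without control 7 days replicate 3, 1 gene passed at 5000 ppm.

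**Figure D3:**
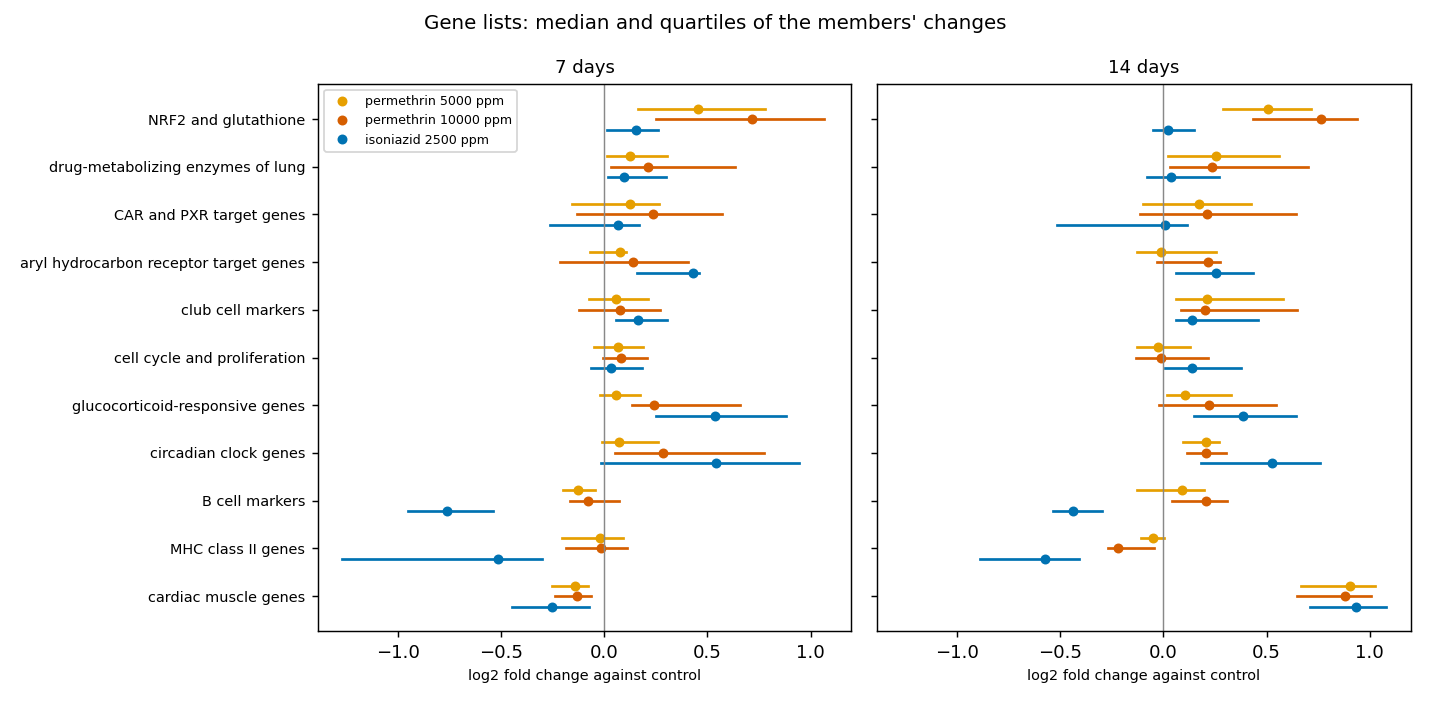
Median (dots) and quartiles (lines) of the members' log2 fold changes against control for 11 gene lists, in panels for 7 and 14 days and in colours for permethrin 5000 ppm, permethrin 10000 ppm and isoniazid. The NRF2 and glutathione list lies at 0.46, 0.71 and 0.15 at 7 days, and the cardiac muscle list at 0.91, 0.88 and 0.93 at 14 days.

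After 7 days of isoniazid Cyp1a1 rose 4.46-fold (log2 2.16, SE 0.37, adjusted p = 0.00778, n = 5 and 5). Alas1, the rate-limiting enzyme of haem synthesis, rose 1.98-fold (log2 0.99, SE 0.13, adjusted p = 0.000103). Metallothionein Mt1 rose 2.02-fold (log2 1.01, SE 0.20, adjusted p = 0.0377) and the selenium-binding protein Selenbp1 rose 1.38-fold (log2 0.46, SE 0.08, adjusted p = 0.00965). Ppp1r3c, a regulator of glycogen synthesis, fell by 0.87 on the log2 scale (SE 0.16, adjusted p = 0.00965), and Scn3b, a subunit of voltage-gated sodium channels, fell by 0.75 (SE 0.15, adjusted p = 0.0377). All 5 treated animals lay on 1 side of the control mean for each of these genes. They were the 6 genes past the threshold (4 higher, 2 lower), with 849 at an unadjusted p under 0.05. Without isoniazid replicate 4 the count was 1, without isoniazid replicate 3, control replicate 1 or control replicate 2 it was 3, and without isoniazid replicate 5 it was 22. Without the 7 arrays of high 3' to 5' ratio, none of which is from 7 days, 14 genes passed. Of the other alternatives, array weights gave 72 genes for isoniazid 2500 ppm against control, 7 days, centring each array on its median 2, and the clock score as covariate, chosen after seeing the data, 0 in limma. With that covariate, which differs between the groups and so widens the errors, the log2 fold change of Cyp1a1 was 2.15 (SE 0.45) and that of Alas1 0.74 (SE 0.14). The calls of Mt1 and Scn3b were each lost under 11 of 22 alternatives.

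As a list at 7 days of isoniazid, aryl hydrocarbon receptor targets were higher (median 0.43, adjusted p = 0.000884 with an estimated correlation), with 2 of 9 past the threshold and 4 adjusted over the list alone. Glucocorticoid-responsive genes were higher (median 0.54, adjusted p = 0.0304 with an estimated correlation), with 1 of 28 past the threshold and 9 adjusted over the list alone. Sodium channel genes were lower (median -0.32, adjusted p = 0.0304 with an estimated correlation), with Scn3b as the 1 of 5 past the threshold, and 1 adjusted over the list alone. Circadian clock genes had 0 of 21 past the threshold, but 11 higher and 2 lower adjusted over the list alone (median 0.54, adjusted p = 0.061 with an estimated correlation). B cell markers had 0 of 23 past the threshold and 11 lower adjusted over the list alone (median -0.76, adjusted p = 0.0777 with an estimated correlation). MHC class II genes, which present antigen, had 0 of 9 past the threshold and 2 lower adjusted over the list alone (median -0.51, adjusted p = 0.061 with an estimated correlation). In the NRF2 and glutathione list 0 of 31 passed, also adjusted over the list alone (median 0.15, adjusted p = 0.464 with an estimated correlation). Cyp2b10 had a log2 fold change of 0.31 (SE 0.09, adjusted p = 0.339), and those of Cyp2f2, Sftpc, Mki67 and Top2a lay between -0.10 and 0.10.

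**Figure D4:**
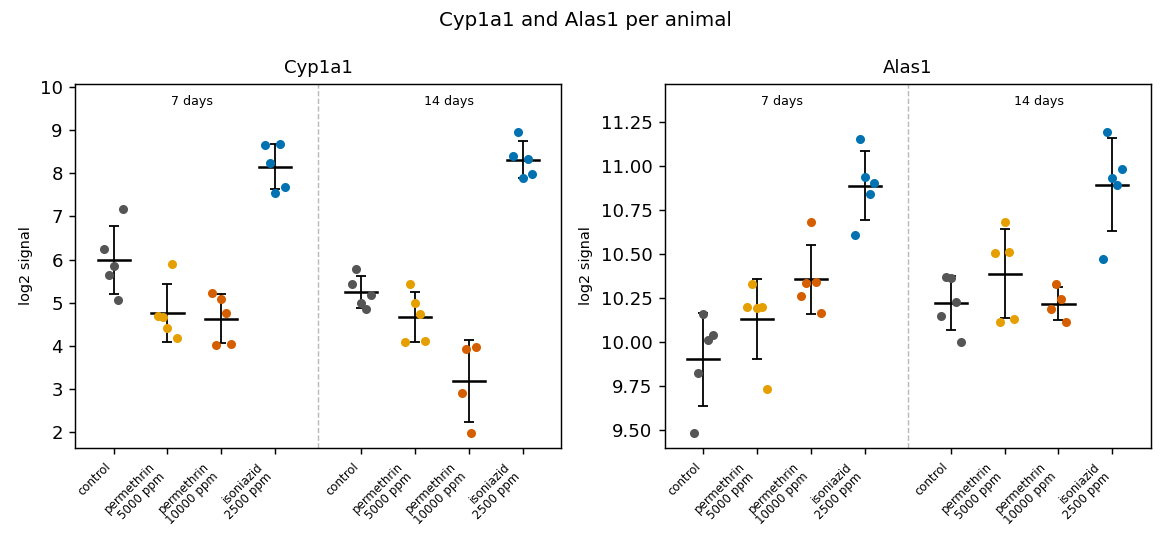
Log2 signal of Cyp1a1 and Alas1 in each animal of the 8 groups, with points for animals, lines for means and bars for SD. Cyp1a1 averages 8.16 at 7 days and 8.32 at 14 days with isoniazid, 5.25 in 14-day controls, and 3.19 with permethrin 10000 ppm at 14 days.

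After 14 days of isoniazid Cyp1a1 rose 8.41-fold (log2 3.07, SE 0.37, adjusted p = 9.05e-06, n = 5 and 5) and Alas1 1.60-fold (log2 0.67, SE 0.13, adjusted p = 0.0351, but 0.35 in its other probe set). Itgae, the integrin of lymphocytes held in epithelium, fell by 1.42 on the log2 scale (SE 0.25, adjusted p = 0.00938), and the carboxylesterase Ces1f fell by 1.36 (SE 0.24, adjusted p = 0.00938). Ces1f is also abundant in liver, and the liver signal of this group was 3.87 against 5.73 in controls. These were the 4 genes past the threshold (2 higher, 2 lower), with 785 at an unadjusted p under 0.05. Of 46 lists, 19 were called with the preset correlation, 0 with an estimated correlation and 1 with fry, the aryl hydrocarbon receptor targets (fry adjusted p = 0.0117, camera adjusted p = 0.0519 with an estimated correlation). Cardiac muscle genes had a median of 0.93, with 0 of 30 past the threshold and 17 adjusted over the list alone (adjusted p = 0.166 with an estimated correlation). Clock genes had a median of 0.52, with 9 higher and 2 lower adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Mki67, a proliferation marker, had a log2 fold change of 0.60 (SE 0.26, adjusted p = 0.768) and Top2a 0.15. Cyp2b10 (log2 0.13), Sftpc (log2 0.11) and Cyp2f2 did not pass, and Scgb1a1 could not be read at the ceiling of the scale. Of 43 cell cycle genes 0 passed in limma, also adjusted over the list alone (median 0.14, preset adjusted p = 0.0019, adjusted p = 0.62 with an estimated correlation). Alas1 lost its call under 13 of 22 alternatives. The count was 1 without control replicate 4 or isoniazid replicate 3, and 2 (Cyp1a1 and Ces1f) without the 7 arrays of high 3' to 5' ratio.

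In the mean of both times 51 genes passed with isoniazid (29 higher, 22 lower), with 1190 at an unadjusted p under 0.05. Cyp1a1 rose 6.12-fold (log2 2.61, SE 0.26, adjusted p = 8.15e-08), the serine protease inhibitor Serpina3n 2.41-fold and the clock gene Per3 2.07-fold (log2 1.05, SE 0.22, adjusted p = 0.0204). Per3 lost its call under 5 of 32 alternatives. Its log2 fold change was 0.08 with the clock score as covariate, but that score includes Per3 itself. The glucocorticoid-induced genes Map3k6 and Fkbp5 both rose by 1.04 on the log2 scale (SE 0.21 and 0.23). With permethrin 10000 ppm the log2 fold changes of Serpina3n, Per3, Map3k6 and Fkbp5 were 0.67, 0.60, 0.77 and 0.72 (SE 0.27, 0.23, 0.22 and 0.24). None of these passed the threshold, but their direction was not particular to isoniazid, whereas Cyp1a1 fell with permethrin. With isoniazid Serpina1c, an antitrypsin made mostly in liver, fell by 2.91 (SE 0.59, adjusted p = 0.0133), with a call lost under 4 of 32 alternatives. With cardiac and liver covariates, chosen after seeing the data, Serpina1c, isoniazid 2500 ppm against control, mean of both times, had a log2 fold change of -1.50 (adjusted p = 0.135, range over its alternatives 0.00277 to 0.714). The liver score also differed by -1.04 at 7 and -1.86 at 14 days (exact permutation p = 0.294 and 0.00794, 0.734 and 0.238 after adjustment). The neutrophil chemokine Cxcl5 fell by 1.70 (SE 0.41). With the clock score as covariate, chosen after seeing the data, its log2 fold change was only -0.29 (SE 0.38). Spon2 fell by 1.30 (SE 0.21, adjusted p = 0.000912, but -0.20 in its other, dimmer probe set), H2-Ob, a class II chaperone subunit of B cells, by 1.24 (SE 0.24, adjusted p = 0.0112) and Hepacam2 by 1.23 (SE 0.23). Glucocorticoid-responsive genes were higher as a list (median 0.44, adjusted p = 0.018 with an estimated correlation), with 3 of 28 past the threshold and 17 higher and 1 lower adjusted over the list alone. Clock genes were higher as a list (median 0.52, adjusted p = 0.018 with an estimated correlation), with 3 higher and 1 lower of 21, and 14 and 2 adjusted over the list alone. Aryl hydrocarbon receptor targets were higher (median 0.36, adjusted p = 0.000789 with an estimated correlation), with 2 of 9 past the threshold and 5 higher and 1 lower adjusted over the list alone. MHC class II genes were lower (median -0.54, adjusted p = 0.0188 with an estimated correlation), with 1 of 9 past the threshold and 4 adjusted over the list alone. B cell markers had a median of -0.57, with 1 of 23 lower and 15 adjusted over the list alone (adjusted p = 0.1 with an estimated correlation). CAR and PXR targets had a median of 0.06 beside a mean of -0.15.

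Without the 7 arrays of high 3' to 5' ratio 19 genes passed for the mean of both isoniazid times, 13 of them among the 51. Centring each array on its median left 18 (7 higher, 11 lower), which turns the balance of directions. Covariates chosen after seeing the data left 13 (cardiac and liver signal) and 2 (clock score). The count was 33 without control 7 days replicate 4 or control 14 days replicate 5, 28 without isoniazid 7 days replicate 2, and 27 without isoniazid 7 days replicate 3 or isoniazid 14 days replicate 5. Cxcl5 lost its call under 23 of 31 alternatives and Fkbp5 under 14 of 32. The isoniazid effect changed between 7 and 14 days for 0 genes in limma, with 384 at an unadjusted p under 0.05. The smallest p-values were those of Tacc3 (log2 change 1.49, SE 0.32, adjusted p = 0.484), Myl3 (1.96, SE 0.45, adjusted p = 0.7), D430019H16Rik (0.78, SE 0.20), Bbc3 (-0.82, SE 0.21) and Ccdc92 (-0.73, SE 0.20). Without isoniazid 14 days replicate 2, 1 gene passed, and the tests on simulated data recovered 64.2% of genes whose effect changed by 1. That share likewise holds for 200 genes changed at once.

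**Figure D5:**
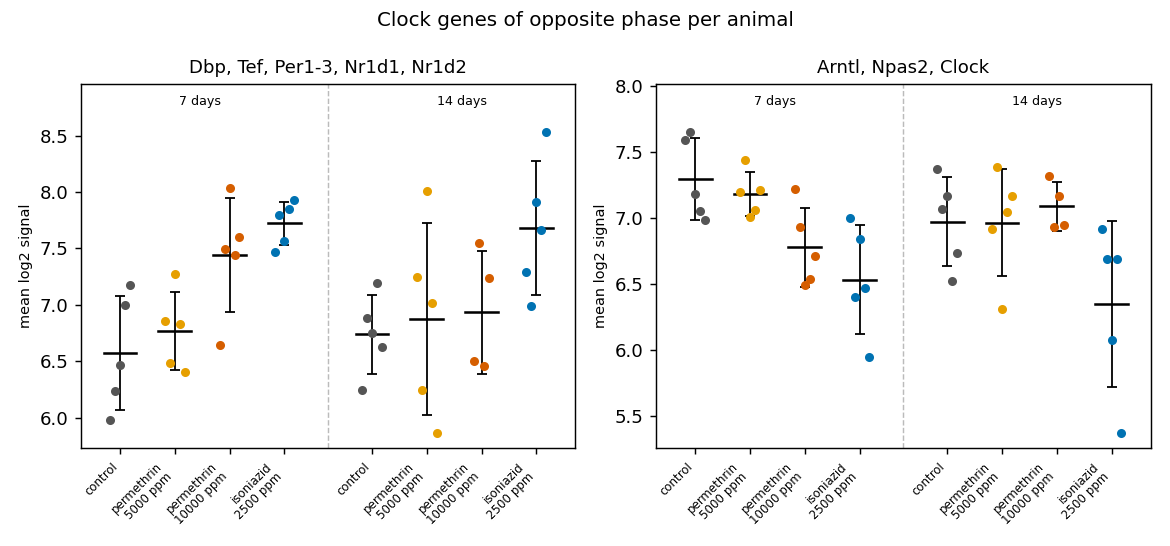
Mean log2 signal of clock genes that peak towards evening (Dbp, Tef, Per1, Per2, Per3, Nr1d1 and Nr1d2) and of Arntl, Npas2 and Clock, which peak in the opposite phase, in each animal, with points for animals, lines for means and bars for SD. With isoniazid the first set differs from controls by 1.05 and the second by -0.69 in the mean of both times.

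Permethrin 10000 ppm and isoniazid differed in 46 genes in the mean of both times (39 higher with permethrin, 7 lower). Ces1g was 7.65-fold higher with permethrin (log2 2.94, SE 0.21, adjusted p = 9.3e-13), Gsta2 4.61-fold, Ces1f 4.23-fold, Aldh3a1 4.01-fold and Nqo1 3.09-fold. Cyp1a1 was lower with permethrin (log2 -4.33, SE 0.27, adjusted p = 6.75e-14, a size made uncertain by a 14-day permethrin mean of 3.19, dimmer than the filter's 3.43), as were Hydin, a gene of motile cilia (-0.71, SE 0.14), Porcn (-0.63, SE 0.13) and Alas1 (-0.60, SE 0.10, adjusted p = 0.000166). Fhdc1 was also lower (-0.58, SE 0.13), with a call lost under 15 of 31 alternatives. The NRF2 and glutathione list was higher with permethrin (median 0.64, adjusted p = 1.03e-07 with an estimated correlation), with 16 of 31 past the threshold and 26 adjusted over the list alone. CAR and PXR targets were higher (median 0.31, adjusted p = 0.000133 with an estimated correlation), with 5 higher and 1 lower of 19, and 6 and 2 adjusted over the list alone. B cell markers were higher with permethrin than with isoniazid (median 0.65, adjusted p = 0.0396 with an estimated correlation), with 1 of 23 past the threshold and 18 adjusted over the list alone. MHC class II genes were higher as well (median 0.35, adjusted p = 0.0457 with an estimated correlation), with 1 of 9 past the threshold and 2 adjusted over the list alone. Cholesterol synthesis genes were lower (median -0.20, adjusted p = 0.0294 with an estimated correlation), with 0 of 20 past the threshold and 5 adjusted over the list alone.

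Treatments of the same time share their controls, so their fold changes across genes correlate even with no common effect, and genes are not independent replicates. At 7 days the correlation across 13020 genes was 0.546 between the permethrin doses, 0.545 between permethrin 10000 ppm and isoniazid and 0.447 between permethrin 5000 ppm and isoniazid. Simulated data without effects gave 0.5, 0.509 and 0.477 (SD over draws 0.15, 0.17 and 0.18). At 14 days the correlations were 0.614, 0.549 and 0.497 against simulated 0.470, 0.458 and 0.477 (SD 0.17, 0.17 and 0.14). At both times each observed value lay within the SD of the simulated ones. These correlations thus cannot tell a common effect from the shared controls. Between the times, which share no controls, the correlation was 0.0278 for permethrin 5000 ppm, 0.201 for 10000 ppm and 0.286 for isoniazid. Permethrin 10000 ppm and isoniazid shared 0 genes called higher at 7 or at 14 days. Isoniazid had only 4 and 2 genes called higher, and independent calls would share 0.00922 and 0.00415. So few calls cannot show whether the compounds change different genes. In the mean of both times Mt1, chosen after its values were seen, rose with both, by 0.80 with permethrin (SE 0.15, adjusted p = 0.00199) and 0.83 with isoniazid (SE 0.14, adjusted p = 0.00359).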

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

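The tests of clock genes, glucocorticoid-responsive genes, cardiac signal and dose below were chosen only after the result was seen, as were the alternatives with covariates or without the 7 arrays of high 3' to 5' ratio.

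Single animals lay far from the others of their group in 33 of 518 groups tested over 65 measures, where chance gives about 5%. At 7 days the log2 signals of these animals were, in controls, 4.65 for Nqo1 (replicate 2), 13.05 for Scgb1a1 and 5.28 for Serpina3n (replicate 1) and 6.26 for Prkab2 (replicate 5), and the mean 3' to 5' log2 ratio of replicate 1 was 0.86. With permethrin 5000 ppm Alas1 was 9.73 in replicate 5. With permethrin 10000 ppm replicate 3 had 8.97 for Fkbp5, 5.05 for Spon2 and 4.38 for Tacc3, replicate 5 had 5.32 for Fetub, and replicate 1 had 7.0 for Adamts5. With isoniazid the values were 5.03 for Top2a (replicate 4), 7.48 for Porcn (replicate 2) and 6.84 for Dubr (replicate 1).

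At 14 days such values in controls were 6.99 for Abcc3, 5.44 for Itgae and a liver score of 4.79 in replicate 2, and 12.01 for Selenbp1, 7.13 for Prkab2 and 3.89 for Serpina3n in replicate 4. With permethrin 5000 ppm replicate 3 had 8.16 for Cbr3, 12.27 for Mgst1, 5.84 for Gm19990 and 3.18 for Kcnip4, and replicate 2 had 3.09 for Capn12. With permethrin 10000 ppm replicate 3 had 11.05 for Gstm1 and 5.82 for Mctp1. With isoniazid replicate 2 had 13.13 for Scgb1a1, 6.30 for Top2a and 4.47 for H2-Ob, replicate 5 had 2.63 for Capn12, replicate 3 had 5.45 for Abcf2, and the liver score of replicate 4 was 3.0. For both values of Scgb1a1 the other animals of the group were tied at the ceiling of the scale, 13.18, so saturation produces the distance.

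Probe sets that match several genes or none were left out of the comparisons, and some of them passed the threshold upward with permethrin. A probe set shared by Gsta2, Gsta1 and a related predicted gene had log2 fold changes of 1.91 and 3.06 at 5000 and 10000 ppm for 7 days, and 1.52 and 2.44 for 14 days. For 3 probe sets shared by the Ugt1a cluster, whose enzymes conjugate glucuronic acid, the values at 7 days were 0.69, 0.72 and 0.72 at 5000 ppm and 0.87, 0.79 and 0.87 at 10000 ppm. At 14 days they were 0.72, 0.75 and 0.67 at 5000 ppm and 0.83, 0.93 and 0.97 at 10000 ppm. A probe set shared by Esd and its pseudogene had 0.48 and 0.73 at 5000 and 10000 ppm for 7 days and 0.65 at 10000 ppm for 14 days. A probe set shared by Cyp2a4 and Cyp2a5 had 2.29 at 10000 ppm for 14 days. A probe set with no gene symbol had 0.88 and 0.95 at 7 days and 1.20 and 1.12 at 14 days.

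Higher NRF2 and glutathione genes with permethrin were set against liver RNA carried over with the lung and against RNA quality. With cardiac and liver signal as covariates the median of the list over both times at 10000 ppm was 0.60, and without the 7 arrays of high 3' to 5' ratio it was 0.78, beside 0.69. Both values argue against these explanations as the whole cause. The list was higher at the higher dose by a median of 0.23 (adjusted p = 0.0388 with an estimated correlation), so a dose-related response to permethrin may explain it. This remains a hypothesis, found and tested on the same animals.

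Higher clock and glucocorticoid-responsive genes with isoniazid were set against a shift in the hour of sampling or in clock phase. Arntl, Npas2 and Clock, which peak in the opposite phase, differed by -0.69 (SE 0.17, exact permutation p = 0.00151, two-sided), so such a shift may explain the pattern. The 25 glucocorticoid-responsive genes outside the clock list had a median of 0.41 and a mean of 0.45 (SE 0.10, exact permutation p = 0.00113). That shows only that the rise was not confined to clock genes, since most of these genes form the pattern itself, and a rise in glucocorticoid action was not tested apart from it. Hours of sampling are not in the labels, and both explanations stay open.

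Higher cardiac muscle genes in the treated groups at 14 days were set against less cardiac muscle in the control samples. The cardiac score of the controls differed by -1.31 between 14 and 7 days (exact permutation p = 0.0238, 0.317 after adjustment, n = 5 and 5), so less cardiac muscle in those samples may explain the pattern. That of the treated groups differed by -0.25 (SE 0.19, permutation p = 0.18, n = 14 and 15). A fall with age or day in all animals, offset by treatment, would give the same values, so a rise with treatment by 14 days cannot be told apart from less cardiac muscle in the controls, and age was not tested.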

How the results depend on the processing

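The deposited scaling, the 3 covariate models and leaving out the 7 arrays of high 3' to 5' ratio were chosen only after the data were seen. No gene named by the rule that passed the threshold, in the main or the alternative run, changed sign. Npas2, named outside the rule, passed for the isoniazid mean (log2 -1.13). It had 0.02 with the clock score as covariate, but that score includes Npas2 itself. Named genes that passed in neither changed sign 25 times when an animal was left out and 15 times under other alternatives. Gsta2, Ces1g, Srxn1 and Txnrd1 kept their calls against control under every alternative. Scgb1a1 at the top of the normalized scale, and genes near its floor, limit what signal over background can show. Every probe set tested gave counts within 1.5 times those reported. Called genes had 23 other probe sets, which gave 46 values over the comparisons, 44 of the same sign. The 2 others came from 1 dim probe set of Srxn1.

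With the deposited scaling isoniazid at 7 days gave 3 genes. With each array centred on its median, permethrin 10000 ppm at 7 days gave 20, isoniazid at 7 days 2 (2 higher, 0 lower, against 4 and 2), permethrin 5000 ppm at 14 days 8 and its mean 18, and the isoniazid mean 18 (7 higher, 11 lower, against 29 and 22). Isoniazid at 14 days then gave 1 higher and 2 lower, against 2 and 2. With only the compared groups in the model, and so fewer animals, isoniazid at 7 days gave 3, permethrin at 14 days 10 and 9 at 5000 and 10000 ppm, isoniazid at 14 days 1 and its mean 25, and the doses differed in 0. With array weights permethrin 5000 ppm at 7 days gave 25, isoniazid 2500 ppm against control, 7 days, 72, permethrin 10000 ppm at 14 days 71, and permethrin 10000 ppm against control, mean of both times, 129, while isoniazid at 14 days gave 2 and the doses differed in 3. For array weights and scalings the cause was not tested. Replicate numbers showed no clear pairing of the animals (7 of 29 correlated best with their own number, correlations from -0.336 to 0.270). A factor shared by some numbers was not ruled out. With the number as a block isoniazid at 14 days gave 7.

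Without the 7 arrays, and so with fewer animals, isoniazid gave 14 at 7 days, 2 at 14 days and 19 for the mean, permethrin 5000 ppm at 14 days 10, and the doses differed in 4. With cardiac and liver signal as covariates permethrin 5000 and 10000 ppm at 14 days gave 5 and 15, the 10000 ppm mean 41 and the isoniazid mean 13. With the clock score as covariate isoniazid gave 0 genes in limma at 7 days, 2 at 14 days and 2 for the mean (of 6, 4 and 51). The median size of those 6, 4 and 51 log2 fold changes went from 0.93, 1.39 and 0.67 to 0.78, 1.35 and 0.42, and their median SE from 0.15, 0.24 and 0.14 to 0.18, 0.27 and 0.16. Since the score differs between the groups, the lost calls do not show that clock phase accounts for these genes. With controls split in 2 the correlation at 7 days was 0.0194 between the permethrin doses, 0.106 between 10000 ppm and isoniazid and -0.00579 between 5000 ppm and isoniazid, and at 14 days 0.184, 0.152 and 0.0827, since treatments then share no controls.

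Medians of some lists reversed. With no filter on dim probe sets, CAR and PXR target genes, permethrin 5000 ppm against control, 7 days, had -0.0357 and for the mean of both times -0.0481. Likewise aryl hydrocarbon receptor target genes, permethrin 10000 ppm against control, 7 days, had -0.0855. B cell markers, isoniazid 2500 ppm against control, 14 days, had 0.032 without the 7 arrays. The causes were not tested. With cardiac and liver covariates, cardiac muscle genes, permethrin 10000 ppm against control, 14 days, had -0.0224 and for the mean of both times -0.0146, but that covariate is the mean of these genes, which fixes a median near 0. Leaving out single animals, aryl hydrocarbon receptor target genes, permethrin 5000 ppm against control, mean of both times, ran from -0.0118 (without control 14 days replicate 4) to 0.0765 and were negative also without control 7 days replicate 2, permethrin 7 days replicate 4 or permethrin 14 days replicate 1.

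Leaving out each animal, permethrin 5000 ppm gave 8 to 12 genes at 7 days, 8 to 16 at 14 days and 27 to 31 for the mean. Permethrin 10000 ppm gave 24 to 29, 17 to 48 and 41 to 74, and isoniazid 1 to 22, 1 to 6 and 27 to 63. The doses differed in 1 to 4 genes, the higher dose and isoniazid in 35 to 59, and effects changed with time for 0 to 1.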

Other observations

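Splits of the arrays, drawn at random with the group sizes kept, were a test planned before the results were seen, and the covariate counts were chosen after. Of 100 splits each, the real one included, those with at least as many genes were 1 for each 7-day comparison, the lowest number possible. That share lay under the bound fixed in advance, so chance is unlikely for these counts. The splits do not speak to single genes. The real counts were 12, 31 and 6 for permethrin 5000 ppm, 10000 ppm and isoniazid, and the highest others 2, 1 and 1. For the means of both times it was 1 each as well, with 29, 65 and 51 genes and highest others of 2, 1 and 4. For permethrin 10000 ppm against isoniazid it was 1, with 46 genes and a highest other of 41, which came near the real count. For the doses it was 4, with 1 gene and a highest other of 1. That share lay under the bound fixed in advance, but 3 other splits tied with the real count, so chance is not firmly excluded there.

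At 14 days the splits were 4 for permethrin 5000 ppm (17 genes, highest other 342) and 3 for 10000 ppm (28 genes, highest other 92). Both shares lay under the bound fixed in advance, but other splits gave far more genes, so the counts do not firmly exclude chance. For isoniazid chance cannot be excluded for the count of genes (9 splits, 4 genes, highest other 913). Cyp1a1, a gene fixed in advance, lost its call there under 0 of 22 alternatives, and at 7 days under 3 of 22. These alternatives keep each animal in its group, and the splits only counted genes, so chance was not tested for Cyp1a1 alone. Splits with several times the real count point to a structure of the samples. In the highest split for permethrin 5000 ppm 4 arrays of high 3' to 5' ratio stood on 1 side and 0 on the other (mean ratio 1.26 and 0.32), and for isoniazid 3 and 1 (1.21 and 0.45), with cardiac scores of 7.22 and 6.59. In that for permethrin 10000 ppm the arrays of high ratio stood 2 and 1 (mean ratio 1.07 and 0.454), and the cardiac scores were 7.53 and 6.32. RNA quality and cardiac signal thus both differed there, and they were not tested apart. With that ratio as covariate 18, 34 and 5 genes passed for permethrin 5000 ppm, 10000 ppm and isoniazid. For the changes of effect from 7 to 14 days all 100 splits had at least as many genes as the real 0, with highest others of 2, 4 and 15. A real count of 0 fixes that outcome, so these splits decide nothing.

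With the clock score as covariate, 2 of the 51 genes passed for the isoniazid mean, and Cyp1a1, isoniazid 2500 ppm against control, mean of both times, kept a log2 fold change of 2.61 (adjusted p = 8.47e-05, the largest over its alternatives). The clock score itself differed from controls by 1.91 with isoniazid at 7 days (exact permutation p = 0.00794, 0.0476 after adjustment, higher in 5 of 5) and by 1.56 at 14 days (exact permutation p = 0.0238, 0.0635 after adjustment, higher in 5 of 5). RNA quality was uneven at 14 days. The 2 isoniazid animals of highest score there (1.84 and 3.17, the others 0.30 to 0.98) and the highest control (0.67) were among the 7 arrays of high 3' to 5' ratio, while the 3 such arrays with permethrin had -0.03, -1.30 and -0.71. No array of 7 days was among them. With permethrin 10000 ppm at 7 days the clock score differed by 1.39 (exact permutation p = 0.0317, 0.0635 after adjustment, higher in 5 of 5).

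Some lists were called with the preset correlation alone in the mean of both times. With permethrin 10000 ppm adipose tissue genes had a median of 0.50 (4 of 25 higher adjusted over the list alone, adjusted p = 0.225 with an estimated correlation) and interferon-stimulated genes -0.18 (0 of 33 in limma, adjusted p = 0.225 with an estimated correlation). With isoniazid ciliated cell markers had a median of 0.24 (5 of 43 higher adjusted over the list alone, adjusted p = 0.45 with an estimated correlation).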
